A study of Mus musculus with 4 samples.

How the data were processed

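Viable CD3+ cells were sorted from digested B16 tumours pooled by genotype, stained with 6 barcoded antibodies and loaded on a 10x Chromium controller with 3' chemistry, per the labels' protocols. The protocol text gives 10 tumours of each genotype and the series description 8 to 10 mice. The labels name the cells as CD8 T cells in 1 place and as CD3+ cells in another, and the counts held CD4, γδ and NK-receptor-expressing cells too. The deposited matrices hold raw UMI counts for 32285 genes and 6 antibody tags per cell barcode, written by Cell Ranger 5.0.0 per the file headers. The reads were aligned to mm10 and Seurat 4.0 is named without a stated role, per the submitters' processing notes. Only barcodes called as cells were deposited, so free RNA and free antibody could not be measured in empty droplets.

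Counts were analysed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Cells with at least 500 genes and under 10% mitochondrial UMIs were kept, 97.6% of WT and 97.2% of KO barcodes, with medians of 5839 and 6451 UMIs. The doublet caller Scrublet, run per library at an expected rate of 6%, marked 0 cells in both libraries and so removed nothing; doublets remain in the data. Both libraries were clustered together without integration, after scaling to 10000 and a log, on 2000 variable genes (T-cell receptor, ribosomal and mitochondrial genes and Lrig1 left out), 30 principal components, 15 neighbours and Leiden resolution 1. CD8 T cells were clustered again at resolution 0.8. Transcripts of Xist gave 3 UMIs in each library and the Y-linked Ddx3y stood at 54.7 and 56.3 CPM, so no difference in sex was seen.

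CD8+ and CD4+ cells were called within each library from a 2-component Gaussian mixture on ln(1 + tag count), whose components lay 3.81 to 4.85 ln units apart. CD8 T cells were CD8+ CD4− cells of conventional T-cell clusters, and CD4 T cells were CD4+ CD8− cells outside the Treg-like clusters. Treg-like cells were all cells of the Treg-like clusters whatever their tags, so a CD8+ CD4− cell there counts in both classes. Clusters with more NK or γδ markers than conventional T-cell markers among their 10 leading genes were kept out of the CD8 and CD4 classes. A cluster led by Pxdc1 and Lmo4 (78 WT and 71 KO cells) matched γδ markers without being led by them. The same held for a cluster led by Klra3 and Mxd3 (0 WT and 12 KO cells). Both counted as conventional T-cell clusters. CD8+ cells made up 37.2% of the WT and 31.1% of the KO cells in the clusters led by NK receptor genes. PD1, TIM3, SLAMF6 and CX3CR1 were scored in CD8 T cells by a mixture over both libraries, after scaling each library to the same median tag total. A cluster of 16 WT and 7 KO cells carried both macrophage and B cell genes and was not given to either type.

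UMIs were summed per gene over the cells of a class in each library and divided by their total (CPM). CPM have exact Poisson intervals, ratios exact conditional binomial intervals, shares exact Clopper-Pearson intervals, differences of shares a square-and-add interval from these, and list medians intervals from 1000 Poisson redraws, all at 95%. These cover counting error only, and UMIs from the same cell or animal are not independent. No test, p-value or standard error was made from cells, since each genotype had 1 library. Genes were counted by size: at least 50 CPM in either library, a ratio of at least 1.5 (or its inverse) and an interval that excludes 1. The median log2 ratio of all 2587 genes with at least 50 CPM in CD8 T cells was 0.01.

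Lists of genes (21) were fixed before the data were examined: progenitor exhausted, terminal exhaustion, cytotoxic effector, proliferation, interferon response, early activation, glycolysis, oxidative phosphorylation, costimulatory receptors, LRIG and receptor tyrosine kinase, VISTA axis, memory and survival, apoptosis, heat shock and dissociation, and markers of melanoma cells, macrophages, B cells, neutrophils, dendritic cells, red cells and fibroblasts. A list's median was taken over members with at least 10 CPM in either library and placed among 10000 random lists matched on expression, as a description of these libraries. Mx1 and Mx2 are not among the features, and 78 features carry a gene symbol that stands on more than 1 identifier. Aldoa is such a symbol and was left out of the glycolysis list. Genes were named by a rule fixed beforehand: Lrig1; the RNA of the antibody panel and Vsir; the 12 highest and 12 lowest ratios in CD8 T cells at 50 CPM whose interval excludes 1, without ribosomal protein, mitochondrial, receptor, immunoglobulin, haemoglobin, Xist, Y-linked and unnamed transcript genes; and up to 4 members of each list (the 2 highest and 2 lowest ratios). Not every gene this rule takes is printed. Rpl9-ps6, Trdc, Tcf7, Cxcl10, Cxcr4, Nr4a1, Igfbp4, Penk, Cd81, Ccl2, Ifitm1, Ifi27l2a, Tff1, Sdc4, Gpr55, Il1r2 and the marker genes that describe clusters were named outside this rule after their values were seen.

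Several choices were made after the data were seen. CD8 clusters took a state name when at least 3 fixed markers stood at 2-fold or more; an earlier rule (3 markers at 1.5-fold, 1 of them among the 10 leading genes) was replaced while the shares in WT and KO were known. Under the earlier rule the cluster led by Penk and Xcl1 was named progenitor exhausted-like and the terminally exhausted-like cluster had no name. The Pdcd1-low Lef1-high group was no planned state: it holds clusters whose markers matched progenitor exhaustion but whose Pdcd1 lay below 0.5 of the CD8 mean. An earlier version of the rule for conventional T-cell clusters, whose gene counts were also seen, wrongly left out the CD8 cluster led by Gzma, Cx3cr1 and S1pr5. Clusters were called doublet-like by doublet score alone (1.5 times the CD8 median or more), because a rule on UMI number would have missed 1 of them. Differences between classes were looked for in the CD8 and CD4 and the CD8 and Treg-like pairs only, a choice made with the list values in view.

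Alternatives fixed before the data were examined were a looser cell filter (200 genes, 20%), no doublet removal, an RNA gate, a median-ratio factor, the mean of each cell's CPM, thinning to 3000 UMIs, equal weight per CD8 cluster, a 10 CPM minimum, lists with no CPM filter, antibody thresholds per library, unscaled tags, and Leiden resolutions 0.5 and 1.2. Equal weight per CD8 cluster always refers to the 9 of 14 CD8 clusters with at least 50 cells of each library, the others being left out. Alternatives added after the data were seen left out the highest 6% of doublet scores (6.79% of WT and 7.60% of KO cells, 486 and 306, because of tied scores), the doublet-like CD8 clusters or the heat-shock-led clusters, took the CD8 gate over all Cd3-expressing clusters, set tag thresholds at percentile 95 of a background population, or used the earlier state rule. The counting rule was tested on simulated data: 50 of 50 genes at 2-fold and 47 of 50 at 1.6-fold were found, 49 of 50 at 0.625 and 50 of 50 at 0.5, with 0 of 2324 unchanged genes called, and 94.3% of ratio intervals held the simulated ratio. The simulation had no variation between animals, so it says nothing about how a second pair of libraries would differ.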

Results

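CD3+ T cells that had infiltrated B16 melanoma, a transplanted mouse tumour, were profiled by CITE-seq, in which mRNA and the oligonucleotide tags of surface antibodies are read from the same cells. The stated aim was the effect of losing LRIG1 on CD8 T cells in the tumour. LRIG1 is a membrane protein with leucine-rich repeats and immunoglobulin-like domains, known as a restraint on receptor tyrosine kinases and as a binding partner of the checkpoint protein VISTA. Tumours were pooled by genotype before loading (10 of each genotype in the labels' protocol, 8 to 10 mice in the series description). Each genotype, wild type (WT) or LRIG1 knockout (KO), therefore had 1 mRNA library and 1 tag library, 4 libraries in all. The WT mRNA library held 7338 cell barcodes and 55421030 UMIs (unique molecular identifiers, single captured transcripts), with a median of 5742 per barcode. The KO mRNA library held 4140 barcodes and 36863722 UMIs, with a median of 6303.5. Tag counts came to 10239266 in WT and 6021443 in KO over 6 antibodies (CD4, CD8, PD1, SLAMF6, CX3CR1 and TIM3). After filtering, 7160 WT and 4024 KO cells were kept. With 1 library per genotype there were no replicates and no test was possible. All 95% intervals below cover counting error only, and no difference was compared with the variation between animals or cell preparations.

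Lrig1, the targeted gene, was sparsely detected in both libraries. Lrig1 (ENSMUSG00000030029) lies on chromosome 6 from 94604529 to 94700298 (GRCm38.p6). In CD8 T cells 55 Lrig1 UMIs were counted in WT and 25 in KO, or 2.46 CPM (counts scaled by the total of the class in that library; 95% interval 1.85 to 3.20) and 1.595 CPM (1.03 to 2.35). The KO/WT ratio was 0.650 (0.388 to 1.06), an interval that held 1. It was 0.628 (0.397 to 0.973) with an RNA gate in place of the tags, 0.565 (0.325 to 0.9498) without the highest doublet scores and 1.19 (0.475 to 2.89) with each cell thinned to 3000 UMIs. Over all cells the counts were 125 and 58 and the ratio was 0.698 (0.502 to 0.960). The 3' tags can come from transcript outside a deleted segment, and the labels do not describe the allele, so these counts do not check the knockout.

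CD8 T cells were taken as cells of conventional T-cell clusters that carried the CD8 tag and not the CD4 tag, 2541 in WT and 1537 in KO. The RNA of the antibody panel differed little between libraries. Cd8a stood at 562 and 546 CPM in WT and KO (ratio 0.972, 0.946 to 0.999), but its log2 ratio was 0.049 with cells thinned to 3000 UMIs and 0.037 as a mean over cells. Pdcd1, which encodes PD1, stood at 172 and 179 CPM (ratio 1.04, 0.986 to 1.09). The ratio was 0.956 (0.874 to 1.05) for Slamf6, 1.07 (0.970 to 1.19) for Havcr2, which encodes TIM3, and 0.869 (0.754 to 1.00) for Cx3cr1. Vsir, which encodes VISTA, had a ratio of 0.999 (0.916 to 1.09). Cd4 gave 4 and 6 UMIs.

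Among 2587 genes with at least 50 CPM in either library, 31 were at least 1.5-fold higher in KO CD8 T cells and 3 were at least 1.5-fold lower, each with an interval that excluded 1. Replication-dependent histone genes made up 8 of the 31. Hist1h4h stood at 38.3 CPM in WT and 108 in KO (ratio 2.81, 2.58 to 3.05), and the ratio was 2.56 for Hist1h2ae, 2.47 for Hist1h4c, 2.28 for Hist1h2ap, 2.25 for Hist1h2ab, 1.83 for Hist1h2bj and 1.74 for Hist1h4d. The metallothionein gene Mt1, which is induced by metals and stress, had a ratio of 2.48 (2.24 to 2.74). The costimulatory receptor gene Icos stood at 38.3 and 64.5 CPM (ratio 1.68, 1.53 to 1.84) and the chemokine receptor gene Ccr2 at 39.2 and 67.8 CPM (ratio 1.73, 1.58 to 1.89). Ratios were 1.65 for the phosphatase gene Dusp1, 1.54 (1.41 to 1.68) for the inhibitory receptor gene Ctla4 and 1.56 (1.51 to 1.62) for Gzmb, which encodes granzyme B. The chemokine gene Ccl1 had a ratio of 2.61, but its 824 KO UMIs came from 21 cells, 450 of them from 1 cell. Its ratio was 9.495 with equal weight given to each CD8 cluster with at least 50 cells of each library. That weighting left out the cluster led by Penk and Xcl1 (112 WT and 40 KO cells), which had the highest Ccl1 level (243 CPM). With the RNA gate 4 of these genes were under 1.5-fold: Ccr2 (1.48), Icos (1.48), Ctla4 (1.39) and Gzmb (1.47). With equal cluster weight Ctla4 (1.44), Gzmb (1.31), Dusp1 (1.41), Hist1h2bj (1.398) and Hist1h4d (1.43) were under it too, and Ctla4 (1.47) also without the heat-shock-led clusters.

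The 3 lower genes were Nrgn (ratio 0.562, 0.512 to 0.617), AC149090.1 (0.656, 0.616 to 0.697) and the ribosomal protein pseudogene Rpl9-ps6; AC149090.1 had ratios of 0.702 as a mean over cells, 0.709 thinned to 3000 UMIs and 0.669 with the gate over all Cd3-expressing clusters. Next in size were Xcl1, a chemokine that attracts dendritic cells (282 and 188 CPM, ratio 0.668, 0.639 to 0.698), Tnfrsf9, which encodes the costimulatory receptor 4-1BB (0.669, 0.622 to 0.719), and Lef1, a transcription factor of naive and memory T cells (0.678, 0.632 to 0.727). Ratios nearer to 1 followed for Rgs10 (0.739), Klf3 (0.740), Tent5a (0.744), Klk8 (0.750), the lymph node homing receptor gene Ccr7 (0.755, but a log2 ratio of 0.041 with equal weight to each CD8 cluster), Rack1 (0.757) and Polr2h (0.774). Rack1, a ribosome-associated scaffold, was also lower in KO in CD4 T cells (0.776), Treg-like cells (0.877), clusters led by NK receptor genes (0.799) and the γδ-led cluster (0.802). In the same order of classes the ratios were 0.68, 0.563, 0.761 and 0.611 for AC149090.1. For Rgs10 they were 0.695, 0.804, 0.675 and 0.611. Rpl9-ps6 was also among the lower genes of Treg-like cells, the clusters led by NK receptor genes and the γδ-led cluster. These genes were therefore not particular to CD8 T cells. Nrgn was lower in Treg-like cells (0.461) but higher in the clusters led by NK receptor genes (1.33, 1.001 to 1.77). As a set the 31 higher genes were higher outside CD8 T cells too. Their median log2 ratio was 0.67 in CD8 T cells, 0.70 in Treg-like cells and 0.70 in CD4 T cells. Over the 25 with at least 10 CPM there, it was 0.59 in the clusters led by NK receptor genes (0.64 in CD8 T cells over the same 25). In the γδ-led cluster it was 0.65, also over 25 genes (0.64 in CD8 T cells over these). At a minimum of 10 CPM the counts were 78 higher and 30 lower. With equal weight given to each of the 9 CD8 clusters that held at least 50 cells of each library, 19 were higher, 14 of them among the 31, and 5 were lower.

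**Figure D1:**
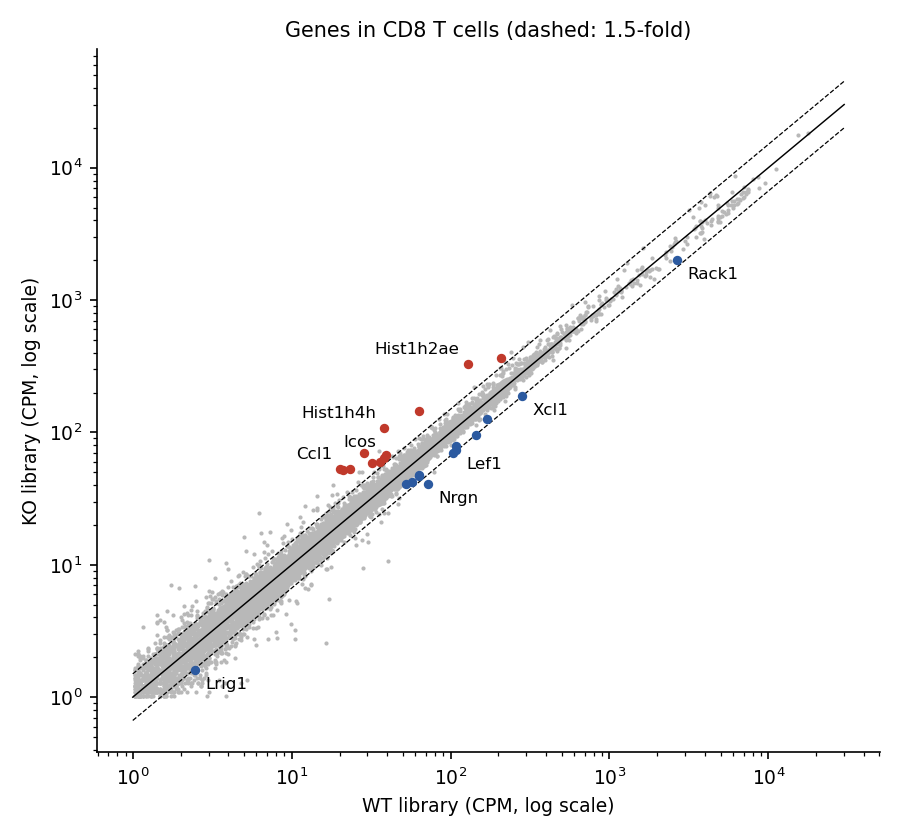
Each grey dot is a gene with at least 1 CPM in CD8 T cells of both libraries, placed by its CPM in the WT library (x axis, log scale) and the KO library (y axis, log scale); the solid line marks equality and the dashed lines 1.5-fold. Red and blue dots mark Lrig1 and the named genes with the 12 highest and 12 lowest ratios among genes with at least 50 CPM in either library and an interval that excludes 1, ribosomal protein, mitochondrial, receptor and unnamed transcript genes among those left out. They run from Hist1h4h at 2.81 to Nrgn at 0.562, and some genes below 50 CPM lie further out.

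Fixed gene lists described the same CD8 T cells. The progenitor exhausted list, named for the self-renewing stem-like pool, also holds Lef1 and Ccr7, which led a naive-like cluster. Its median log2 ratio in KO was −0.20 (−0.24 to −0.13) over 17 members, at percentile 0 of 10000 random lists matched on expression. With equal weight to each CD8 cluster it was 0.04, and the list does not single out progenitor exhausted cells. Of the 17 members 9 had an interval below 1, among them Tcf7 (ratio 0.826) and Il7r (0.873), while Cd28 was above 1 (1.18). Slamf6 (0.956, 0.874 to 1.05) and Myb (1.16, 0.992 to 1.36) had intervals that held 1. The terminal exhaustion list had a median of 0.05 (0.00 to 0.11, percentile 77.9), with 8 of 21 members above 1 and 4 below. Its members parted: Ctla4 (1.54) and Rgs1 (1.36) were higher, and Tnfrsf9 (0.669) and Cd244a (0.729) lower. The cytotoxic list had a median of 0.06 (−0.01 to 0.11, percentile 91.8), with Klrg1 at a ratio of 2.18 (1.82 to 2.60) and Gzmb at 1.56 against Gzmd at 0.303 (0.219 to 0.412) and Gzme at 0.262 (0.184 to 0.363). Klrg1 had a ratio of 1.36 with the RNA gate, and thinned to 3000 UMIs the ratios were 0.7996 for Gzmd and 0.149 for Gzme.

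The medians of the proliferation, interferon and early activation lists were above 0 in KO over all CD8 T cells. The proliferation list had a median log2 ratio of 0.24 (0.18 to 0.26, percentile 100) but −0.12 with equal weight to each CD8 cluster, with 19 of 29 members above 1, led by Ccna2 (ratio 1.43) and Nusap1 (1.41). Mcm3 was lower (0.876), and Mcm2 had a ratio of 0.896 (0.783 to 1.02). The interferon list had a median of 0.19 (0.11 to 0.22, percentile 100), with 13 of 26 members above 1, 2 below and none at 1.5-fold, and a median of 0.090 with equal cluster weight. Rsad2 (1.49) and Gbp4 (1.45) stood highest, and Bst2 (0.831) and Isg15 (0.869, but a log2 ratio of 0.017 thinned to 3000 UMIs) lowest. The early activation list had a median of 0.23 (0.17 to 0.29, percentile 100), with 15 of 21 members above 1, among them Dusp1 and the immediate early gene Fos (1.54). The Fos ratio was under 1.5 in 5 alternatives: 1.296 without doublet-like CD8 clusters, 1.34 with the looser cell filter, 1.41 with equal cluster weight, 1.43 without the highest doublet scores and 1.47 with the gate over all Cd3-expressing clusters. Ier5 (0.908) was lower and Myc had a ratio of 0.934 (0.833 to 1.05). Fos was also higher in KO in every other class, with ratios from 1.70 in the clusters led by NK receptor genes to 2.35 in the γδ-led cluster. The early activation list as a whole was not particular to CD8 T cells. Its median was 0.31 in CD4 T cells and 0.28 in Treg-like cells. In the clusters led by NK receptor genes it was 0.29, and in the γδ-led cluster 0.63.

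Of the metabolic lists, glycolysis genes had a median log2 ratio of −0.01 (−0.03 to 0.03, percentile 25.15), with Hk2 at a ratio of 1.70 and Bnip3 at 1.40 against Slc2a3 at 0.883 and Pfkl at 0.911. Oxidative phosphorylation genes had a median of 0.10 (0.08 to 0.12, percentile 99), with 24 of 38 members above 1 and 6 below. They ran from Atp5k (1.59, or 1.497 with equal cluster weight) and Cox7c (1.38) to Atp5b (0.856) and Cox4i1 (0.888). This list was not particular to CD8 T cells. Its median was 0.13 in CD4 T cells, 0.04 in Treg-like cells, 0.06 in the clusters led by NK receptor genes and 0.15 in the γδ-led cluster. Atp5k had ratios from 1.53 to 1.64 in these classes. In CD8 T cells the medians were −0.02 for costimulatory receptors (Slamf1 1.49, Tnfrsf4 0.806), 0.04 for the VISTA axis (Lgals9 1.03, Selplg 1.04), and 0.08 for memory and survival (Runx3 1.33, Bcl2 0.893). They were 0.07 for apoptosis (Pmaip1 1.35, Cdkn1a 1.31, Bbc3 0.919) and 0.06 for heat shock and dissociation genes (Hspa1a 1.204, Hsph1 1.196, Hsp90ab1 0.928, Hspa8 1.01). Hspa1a was lower in KO with equal weight to each CD8 cluster (0.684) and without the heat-shock-led clusters (log2 −0.26). The equal weighting also left out the CD8 cluster led by Hspb1 and Hspa1a (29 WT and 34 KO cells). No gene of the LRIG and receptor tyrosine kinase list reached 10 CPM, and together they gave 13.8 CPM in WT and 11.9 in KO. With equal weight to each CD8 cluster the progenitor median was 0.04, the terminal exhaustion median −0.03 and the proliferation median −0.12, each of opposite sign. With an RNA gate in place of the tags the terminal exhaustion median was −0.0049, and as a mean over cells it was 0.22.

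Markers of several other cell types were scarce in the CD8 class. Summed levels in WT and KO were 2.59 and 1.08 CPM for melanoma genes, 7.77 and 8.17 for macrophage genes, 0.491 and 0.638 for neutrophil genes, 0.536 and 0.766 for red cell genes and 0.223 and 0.383 for fibroblast genes. B cell genes were not scarce, with a sum of 151 CPM in WT and 130 in KO; Ighm and Igkc stood at 82.1 and 61.6 CPM in WT, with a list median log2 ratio of −0.22 over 2 members. Dendritic genes summed to 47.6 and 39.9 CPM, and Cd74, the 1 of them at 10 CPM, had a ratio of 0.813 (log2 0.21 with equal cluster weight). Trdc, the constant segment of the T-cell receptor δ chain, stood at 35.4 and 72.0 CPM in CD8 T cells (ratio 2.03, 1.85 to 2.23). The γδ-led cells were a larger share of the KO library (3.23% of WT and 7.73% of KO cells). Clusters that matched γδ markers without being led by them counted as conventional T-cell clusters, from which the CD8 class was taken. The CD8 cluster led by Tmem176a (15 WT and 24 KO cells) had 404 CPM of Trdc. Without it and the CD8 cluster led by Fcer1g and Klra1 the Trdc ratio was 1.86 (1.65 to 2.09). The CD8 cluster led by Fcer1g and Klra1, with a median of 12804 UMIs per cell, and the cluster led by Tmem176a had the highest doublet scores. They held 194 WT and 222 KO cells together. Without them 31 genes were again higher, 24 of them shared, 7 in place of 3 were lower, and the progenitor and proliferation medians were −0.37 and 0.38.

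**Figure D2:**
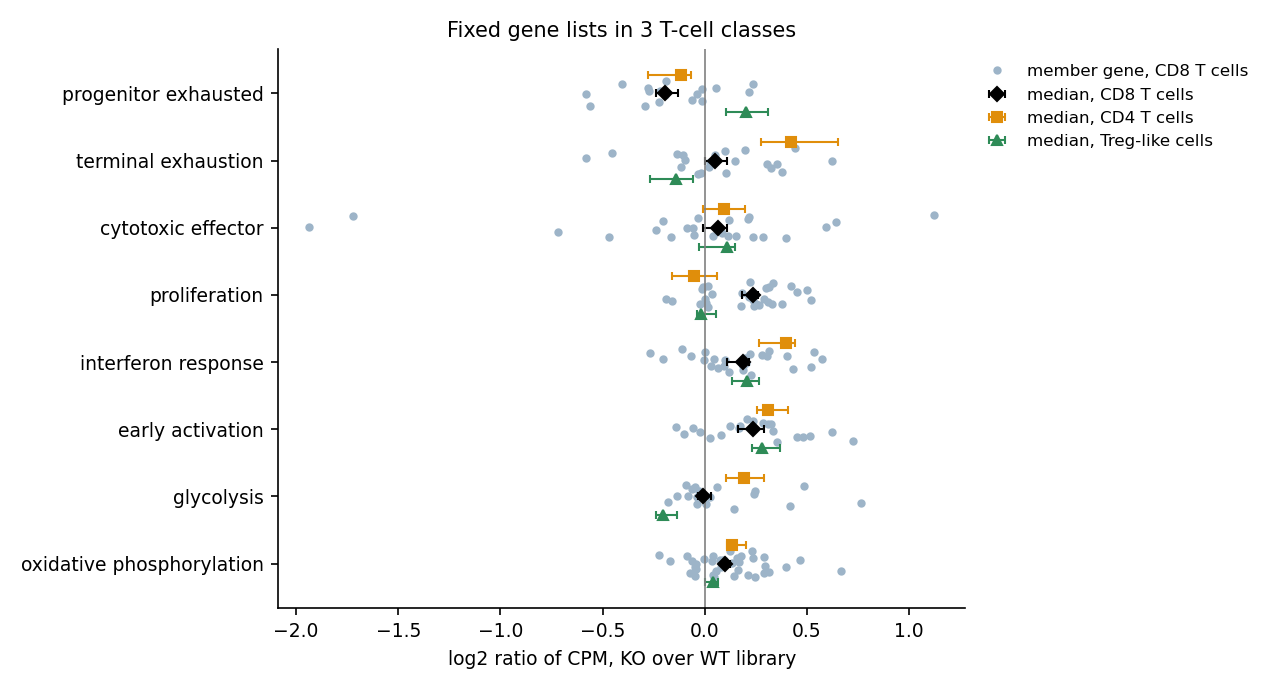
The x axis gives the log2 ratio of CPM, KO over WT library, for 8 fixed gene lists; small dots are single members in CD8 T cells, and large symbols are list medians in CD8, CD4 and Treg-like cells with 95% intervals from Poisson redraws (counting error only). The progenitor exhausted median was −0.20 in CD8 T cells and 0.20 in Treg-like cells, and the early activation median was above 0 in all 3 classes.

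Surface tags separated PD1 and TIM3 more clearly than CX3CR1. With 1 threshold per marker over both libraries, SLAMF6+ TIM3− cells made up 48.8% (46.8 to 50.8) of WT and 51.6% (49.1 to 54.1) of KO CD8 T cells, a difference of 2.79 points (−0.41 to 5.99). This gate set no condition on PD1 and does not single out progenitor exhausted cells: the 2 Pdcd1-low Lef1-high clusters had median SLAMF6 tag counts of 13 and 19 and TIM3 of 6 and 7. TIM3+ SLAMF6− cells made up 10.6% of WT and 14.3% of KO, 3.73 points higher (1.599 to 5.92). PD1+ cells made up 46.4% and 52.0%, 5.59 points higher (2.38 to 8.78). The 2 Pdcd1-low Lef1-high clusters, with median PD1 tag counts of 4.5 and 5, were 29.4% of WT and 15.1% of KO CD8 T cells. More PD1 per cell was not told apart from this difference in make-up. The median PD1 tag count was 15 and 19 over all CD8 T cells but 52 and 45.5 in terminally exhausted-like cells. CX3CR1+ cells made up 84.5% and 53.4%, a difference of −31.2 points (−34.1 to −28.3), but this tag had no separate positive population: its fitted components lay 0.358 ln units apart, against 1.90 for PD1 and 1.49 for TIM3. With thresholds set within each library the differences were −1.50 points for SLAMF6+ TIM3−, 7.09 for TIM3+ SLAMF6−, 12.4 for PD1+ and 6.20 for CX3CR1+. The median CX3CR1 tag count was lower in KO in every class scored, for example 9 and 5 in CD4 T cells, and the TIM3 tag likewise stood at 7 and 4 in the clusters led by NK receptor genes.

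**Figure D3:**
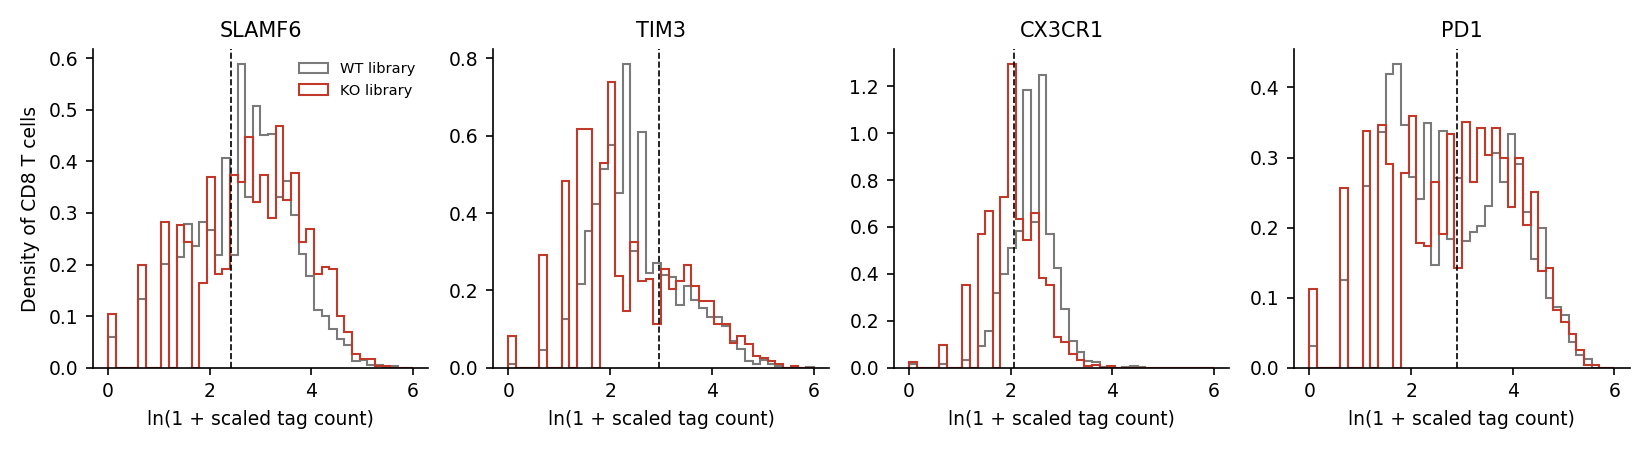
Each panel shows the density of CD8 T cells over ln(1 + scaled tag count) for 1 antibody, with the WT library in grey and the KO library in red; the dashed line is the threshold over both libraries. PD1 and TIM3 have a second population, whereas CX3CR1 shows 1 peak that lies lower in KO.

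The make-up of the T cells differed between the libraries. CD8 T cells made up 48.5% (47.1 to 49.8) of WT and 54.3% (52.4 to 56.1) of KO cells in conventional T-cell clusters, 5.83 points higher in KO (3.52 to 8.12). When clusters led by NK receptor or γδ genes were counted as T cells the difference was 1.16 points, with an interval that held 0 (−0.77 to 3.10). Of all cells, CD4 T cells outside the Treg-like clusters made up 12.6% and 9.54%, and Treg-like cells, which express the regulatory T-cell factor Foxp3, 16.8% and 11.9%. Clusters led by NK receptor genes made up 23.3% and 21.7%, and a γδ-led cluster, whose leading genes were Il17a and Cd163l1, 3.23% (2.83 to 3.66) and 7.73% (6.92 to 8.60). Cells with both the CD4 and the CD8 tag made up 8.77% and 9.77%; their median UMI numbers of 12620.5 and 15926 exceeded those of CD8 T cells (6937 and 7399).

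Within CD8 T cells the clearest difference in state was in cells with low Pdcd1 and high Lef1, a naive- or memory-like profile: 29.4% (27.7 to 31.3) in WT and 15.1% (13.3 to 17.0) in KO, or −14.3 points (−16.9 to −11.8). An earlier naming rule gave −8.51 points; it added the cluster led by Fcer1g and Klra1, whose Pdcd1 level (138 CPM) was not low. Proliferating-like cells made up 11.02% and 14.0% (2.97 points, 0.84 to 5.16), or 0.666 points more under the earlier rule. Terminally exhausted-like cells, named by Havcr2, Lag3, Entpd1 and Tox but led by Gzmf, Gzmd, Gzme, Gzmc and Prf1, made up 13.5% and 12.2% (−1.31 points, −3.43 to 0.87). Interferon-like cells made up 3.503% and 4.03% (0.531 points, −0.69 to 1.83). Effector-like cells, marked by Cx3cr1, Klrg1 and S1pr5, made up 3.19% and 1.89% (−1.30 points, −2.28 to −0.26). The remaining 39.3% and 52.8% matched none of these states. No cluster matched the progenitor exhausted state under the rule used; under the earlier rule a cluster led by Penk and Xcl1 did, with 4.41% and 2.60%. Inside each state the state's own markers had median log2 ratios from −0.10 (−0.27 to −0.01) in the Pdcd1-low cells to 0.10 in interferon-like cells, and single markers ranged from −0.78 to 1.03 in effector-like cells and from −0.13 to 0.02 in proliferating-like cells.

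**Figure D4:**
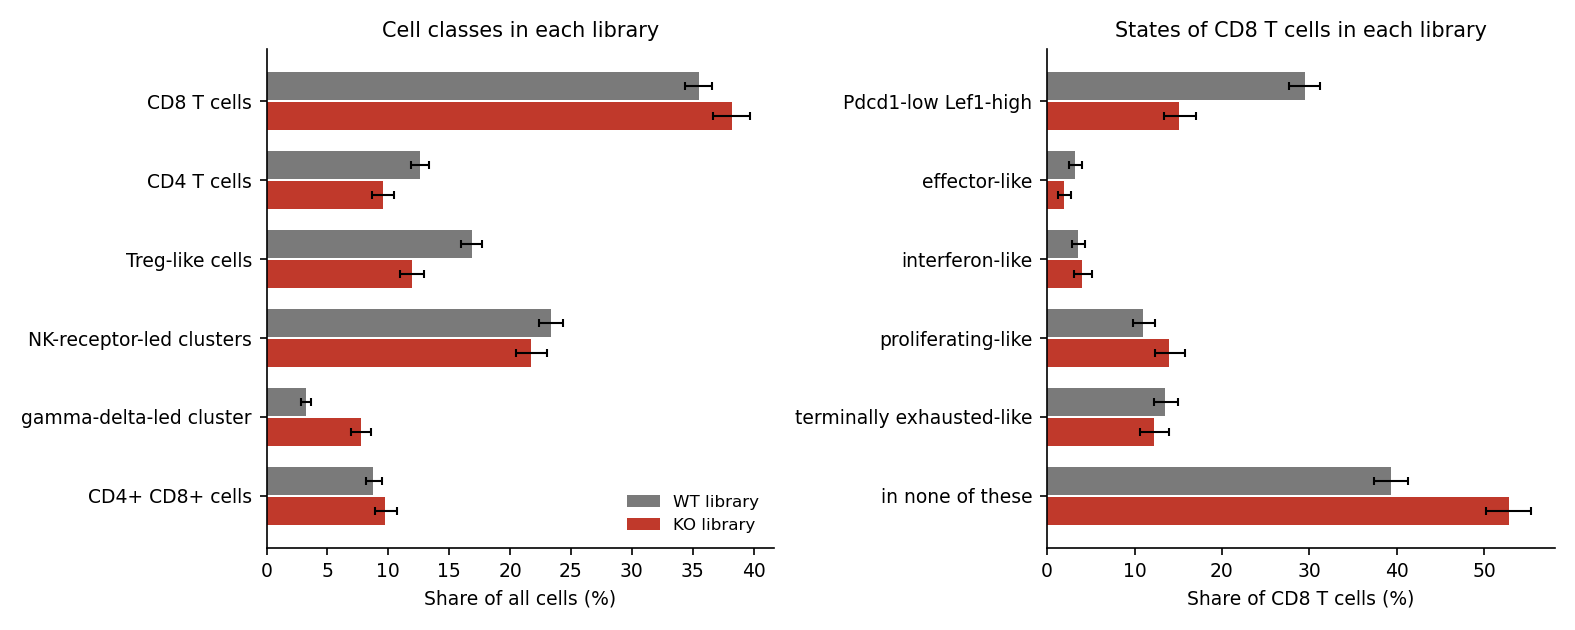
Bars start at 0 and give the share of all cells in each class (left, %) and the share of CD8 T cells in each state (right, %) in the WT library (grey) and the KO library (red); error bars are exact 95% binomial intervals. The γδ-led share was 3.23% in WT and 7.73% in KO, and the Pdcd1-low Lef1-high share 29.4% and 15.1%.

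CD4 T cells (901 in WT, 384 in KO) gave 68 genes at least 1.5-fold higher and 19 lower in KO. Higher genes included Fos (123 and 283 CPM, ratio 2.29), the chemokine receptor gene Cxcr4 (2.61), Nr4a1, induced by T-cell receptor signalling (2.27), and Ctla4 (1.93, 1.601 to 2.34). Lower genes included Lef1 (221 and 102 CPM, ratio 0.462) and Igfbp4 (0.422). List medians were 0.42 (0.28 to 0.65) for terminal exhaustion, 0.40 for interferon response, 0.31 for early activation, 0.27 for costimulatory receptors, 0.19 for glycolysis and −0.12 for progenitor genes. The cluster led by Ccr7 and Lef1, a naive-like profile, held 21.9% of WT and 10.9% of KO CD4 T cells, and 8.97% and 3.71% of CD8 T cells.

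Treg-like cells (1206 and 480) gave 56 higher and 23 lower genes. The interferon-induced chemokine gene Cxcl10 stood at 21.9 and 106 CPM (ratio 4.83, 4.12 to 5.67), and Slamf6 had a ratio of 1.53 (1.33 to 1.75). Cd81 stood at 211 and 70.4 CPM (ratio 0.333, 0.296 to 0.374), the enkephalin precursor gene Penk at 151 and 48.1 CPM (0.319), and Havcr2 (0.566), Klrg1 (0.593) and Tnfrsf9 (0.737) were also lower. List medians were 0.28 for early activation, 0.21 for interferon response, 0.20 (0.10 to 0.31) for progenitor genes, −0.14 (−0.27 to −0.06) for terminal exhaustion and −0.20 (−0.24 to −0.14) for glycolysis. Their Cd8a level was higher in KO (85.4 and 118 CPM, ratio 1.38, 1.24 to 1.54) and Cd4 lower (0.809, 0.728 to 0.899), and their mean CD8 tag count was 325 and 499. By tag, SLAMF6+ TIM3− cells made up 43.8% of WT and 70.8% of KO Treg-like cells, and PD1+ cells 68.0% and 51.0%. These shares used thresholds fitted on CD8 T cells, and no threshold per library was set for Treg-like cells. The median TIM3 tag count was lower in KO in CD4 T cells (7 and 4) and the γδ-led cluster (8 and 4) too. The differences between CD8, CD4 and Treg-like cells were not tested.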

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

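Tests of gene length, of naive-type CD4 T cells and of CX3CR1 background were chosen after the result was seen. Those of the same genes in other classes, of cycling cells and of UMI depth were written before. The split of the cycling test into histone and other genes came after. The pairs of classes compared were also chosen with the values in view.

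The γδ-led cluster, kept out of the CD8 class, held 7.73% of KO and 3.23% of WT cells, with intervals that do not overlap. Opposite signs in 2 classes marked the next values, and none of these differences was tested. The progenitor exhausted list had a median log2 ratio of 0.20 in Treg-like cells and −0.20 in CD8 T cells. The terminal exhaustion list had −0.14 in Treg-like cells and 0.05 in CD8 T cells. The B cell list had 0.32 in Treg-like cells (3 members) and −0.22 in CD8 T cells (2 members), and the dendritic list 0.74 in CD4 T cells and −0.30 in CD8 T cells (1 member each). Several of these signs in CD8 T cells hung on the processing: with equal weight to each CD8 cluster the progenitor median was 0.041, the terminal exhaustion median −0.032 and the log2 ratio of Cd74, the dendritic member, 0.21, and with the RNA gate the terminal exhaustion median was −0.0049. TIM3+ SLAMF6− cells differed by −4.19 points, KO minus WT, in Treg-like cells and by 3.73 in CD8 T cells. PD1+ cells differed by −17.0 points in Treg-like cells and by 5.59 in CD8 T cells. These tag shares used thresholds fitted on CD8 T cells, and no threshold per library was set for Treg-like cells. Where PD1 tags were few the median was also lower in KO, 5 and 2 in CD8 T cells of the Ccr7- and Lef1-led cluster. The RNA of Pdcd1 (ratio 0.858) and Havcr2 (0.566) was lower in Treg-like cells too. Tag background and a difference between classes were therefore not told apart.

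Genes higher in KO CD8 T cells were weighed against 3 technical explanations. Outside the proliferating-like clusters 28 of the 31 genes kept a median log2 ratio of 0.66 (0.63 to 0.70); more cycling cells were argued against as the whole cause for the 23 genes other than histones (0.65, 0.62 to 0.69, against 0.64 over all CD8 T cells) and left open for the 8 histone genes (0.74, 0.62 to 1.02, against 1.18). The cells outside still held a small CD8 cluster with Mcm3 of the proliferation list among its leading genes (25 WT and 21 KO cells). The 31 genes had been chosen over all CD8 T cells, those outside the proliferating-like clusters among them. A difference in how the whole library captured transcripts may account for part of the 31 genes. The medians were 0.70 in Treg-like cells and 0.70 in CD4 T cells. They were 0.59 in the clusters led by NK receptor genes (25 of the 31) and 0.65 in the γδ-led cluster (25 of the 31). In neither Treg-like cells nor the clusters led by NK receptor genes did 12 of them meet the rule of size. Of these 12, 7, Icos, Ctla4 and Gzmb among them, met it in CD4 T cells or the γδ-led cluster. Icos (1.03 and 0.939) and Gzmb (0.934 and 0.814) were not raised in Treg-like cells and the clusters led by NK receptor genes. Ccr2, Ccl1, Trdc, Hmgn2 and Hist1h2be met the rule in no other class. Favoured short transcripts were left open. The length used was the gene's span on the genome, introns included, so short transcripts of longer genes did not count as short. Genes with a span under 1 kb exceeded those over 10 kb by 0.24 (−0.07 to 0.39) in CD8 T cells, with 36 short genes. In the clusters led by NK receptor genes they did so by 0.059 (−0.01 to 0.39), with 26 short genes. Of 30 higher genes with a length, 9 were under 1 kb, 6 of them histones, against 1.403% of all tested genes with a length. An effect of LRIG1 loss shared by several T-cell classes also predicts that the same genes are higher in other classes. With 1 library per genotype, genotype and preparation stay together.

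The smaller share of CD8 T cells in the cluster led by Ccr7 and Lef1 in KO was weighed against blood or lymph node cells in the WT preparation and against depth. In the clustering of all cells, CD4 T cells of this cluster were also a smaller share in KO, with a KO/WT ratio of 0.5002 (0.367 to 0.683), so a difference in such cells between preparations may account for the share. In the clustering of CD8 T cells alone the ratio was 0.427 (0.325 to 0.561), and after thinning, which left out 120 WT and 89 KO cells, and clustering again it was 0.542 (0.433 to 0.678), below the 0.8 that depth as the cause needed but not wholly below the 0.6 set beforehand as the bound against it. A bound of 0.8 was tried in its place after the value was seen and was not kept. Fewer naive-like cells in KO tumours, the biological explanation, stays open and untested.

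The lower CX3CR1+ share of KO CD8 T cells may come from higher background of this tag in WT: with the same threshold the share differed by −35.5 points in Treg-like cells and by −43.6 points in the γδ-led cluster, against −31.2 in CD8 T cells. Thresholds set within each library turned the CD8 difference to 6.20 points. The tag hardly followed Cx3cr1 RNA. Effector-like CD8 T cells, marked by Cx3cr1, had median tag counts of 11 in WT and 7 in KO, as had CD8 T cells as a whole. In the γδ-led cluster Cx3cr1 stood at 0 CPM in WT and 4.38 in KO, while 83.1% and 39.5% of cells were scored positive. A change in CX3CR1 protein with genotype therefore cannot be read from this tag and stays open. No control without antibody was used here.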

How the results depend on the processing

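Alternatives on doublet scores, doublet-like or heat-shock-led clusters, Cd3-expressing clusters, background thresholds and the earlier state rule were chosen after the data were seen; the others were fixed beforehand. Leaving out the setting with no doublets removed, which gave the values already reported since none had been marked, of 181 main values under alternatives 135 stayed within their interval (or 1.5 times for counts), 40 moved outside it and 6 reversed; of 769 values of named genes the numbers were 651, 111 and 7. Where a value moved or reversed the cause was not tested. No paired analysis was possible because each genotype had 1 pooled library. Lrig1 had few UMIs in CD8 T cells, 55 in WT and 25 in KO, and its ratio had a wide interval (0.388 to 1.06).

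Gene lists are given as median log2 ratios, single genes as log2 ratios and shares as points, KO minus WT. With equal weight per CD8 cluster the progenitor (0.041), terminal exhaustion (−0.032) and proliferation (−0.12) lists, Ccr7 (0.041), Cd74 (0.21) and Hspa1a (−0.55) reversed; cytotoxic (−0.033), interferon (0.090) and oxidative phosphorylation (0.058) lists moved, with 19 genes higher and 5 lower. With the RNA gate terminal exhaustion reversed (−0.0049), and early activation (0.30), glycolysis (−0.056) and proliferation (0.18) moved. Thinned to 3000 UMIs, Cd8a (0.049) and Isg15 (0.017) reversed; Lrig1 (ratio 1.19), early activation (0.29), proliferation (0.28), terminal exhaustion (0.16) and the lower genes (5) moved. With the mean of each cell's CPM Cd8a reversed (0.037), and cytotoxic (0.12) and terminal exhaustion (0.22) moved. The looser filter gave proliferation 0.26, the median-ratio factor 5 lower genes, and 10 CPM 78 higher and 30 lower genes.

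Thresholds within each library reversed CX3CR1+ (6.20) and moved PD1+ (12.4), SLAMF6+ TIM3− (−1.50) and TIM3+ SLAMF6− (7.09); background thresholds gave 5.63, reversed, then 16.7, −0.79 and 11.1. The Pdcd1-low share was −11.0 at resolution 1.2 and −8.51 under the earlier state rule, which gave 0.666 for proliferating-like cells. With the gate over all Cd3-expressing clusters the CD8 share was 1.16, SLAMF6+ TIM3− −0.61 and proliferation 0.29. Without the highest doublet scores CX3CR1+ was −24.6 and 5 genes were lower. Without doublet-like clusters CX3CR1+ was −34.4, early activation 0.16, glycolysis 0.064, oxidative phosphorylation 0.14, progenitor −0.37 and proliferation 0.38, with 7 lower genes. Without heat-shock-led clusters Hspa1a reversed (−0.26).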

Other observations

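These values were noticed after the data were seen and were not tested. In the γδ-led cluster (231 WT and 311 KO cells) Cxcl10, an interferon-induced chemokine gene, stood at 34.0 CPM in WT and 537 in KO, a ratio of 15.8 (11.6 to 22.0), with at least 1 UMI in 6.49% and 20.6% of cells. Cxcl10 ratios were 4.83 in Treg-like cells, 1.85 in CD4 T cells, 1.56 in the clusters led by NK receptor genes and 1.18 in CD8 T cells, where 3.66% and 6.05% of cells had a UMI. In the γδ-led cluster the interferon gene Isg15 (ratio 2.54), Ifi27l2a (2.76), Gzmb (2.94) and Dusp1 (3.00) were also higher. So were Cd8b1 (1.73, 1.29 to 2.34), a gene of CD8 T cells, and Nkg7 (1.62), Ccl5 (1.61) and Ly6c2 (1.52). In WT CD8 T cells Nkg7, Ccl5 and Ly6c2 stood at 1700, 5912 and 828 CPM. In the WT clusters led by NK receptor genes they stood at 990, 4494 and 1764 CPM. Cd8a had a ratio of 1.32 (0.990 to 1.78) in the γδ-led cluster, and the mean CD8 tag count was 139 in WT and 201 in KO. List medians of the γδ-led cluster were 0.63 for early activation, 0.57 for cytotoxic genes and 0.46 for interferon response, and Trdc itself had a ratio of 0.808. Lower genes there included Sdc4 (0.498) and the heat shock gene Hspa1a (0.505).

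In Treg-like cells Cd81, a tetraspanin, had at least 1 UMI in 55.2% of WT and 31.2% of KO cells (median depths 6495 and 6726 UMIs), against 0.659% and 0.686% in the clusters led by NK receptor genes (median depths 5316.5 and 5935). Tff1 (0.253), Sdc4 (0.416), Gpr55 (0.438) and the decoy receptor gene Il1r2 (0.464) were also lower in KO Treg-like cells. Penk was lower in KO in Treg-like (0.319) and CD8 T cells (0.338, where 208 of 626 WT UMIs came from 1 cell), and had a ratio of 2.32 in CD4 T cells, where 83 of its 88 KO UMIs came from 1 cell. Single cells set other values: 539 of 541 Ccl2 UMIs in WT Treg-like cells came from 1 cell, and Ifitm1 in CD4 T cells (ratio 7.24) came from 13 KO cells.

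UMIs of all histone genes, summed, had a KO/WT ratio of 1.504 in CD8 T cells, 1.38 in Treg-like cells, 1.28 in proliferating-like CD8 T cells and 0.967 (0.886 to 1.06) in the γδ-led cluster. A small heat-shock-led cluster held 0.321% of WT and 1.12% of KO cells, with median depths of 1978 and 1454 UMIs.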
